A study of Mus musculus with 10 samples.

How the data were processed

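Reduced representation bisulfite sequencing was used on bone marrow LSK cells of NZB/W mice, with 4 lupus and 6 prediseased samples. Trim Galore 0.6.4, Bismark 0.23.1, Bowtie2, methylKit and the build mm10 are named in the submitters' processing notes, without their order, parameters or coverage minimum. The authors deposited a single table with the percent methylation of each sample in tiles of 1000 bp. It holds 197568 tiles on 21 chromosomes, with no missing value, from 0 to 100 percent, and no coverage or read counts. Whether the tiles were first restricted to those covered in all samples is not given in the sources used here. The depth per sample is unknown, so values from few and from many reads count alike and no counting error can be given. A tile value averages whichever CpGs were read in that sample, so a change in the CpGs covered also moves it. The share of tiles at exactly 100 percent differed between samples, from 1.30% in prediseased S1 to 12.3% in lupus S1.

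Each column was matched to the sample whose title opens with the same code. Column names end in sample numbers: 1310 to 1316 for the samples of Set2 and 1149, 1150 and 1152 for the other 3. No 2 columns were identical. Groups follow the titles and the condition label. The title set was treated as a possible batch: all lupus samples are in Set2, so overall methylation was compared within Set2, and fits over all 10 samples carried the set as a term.

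Tiles were annotated with a RefSeq gene table of GRCm38, the assembly named mm10 by the submitters, using 21900 protein-coding and 12731 lncRNA genes. That table gives the start and end of a gene but not its strand or exons, so promoters, exons and introns could not be told apart. The planned promoter analysis was therefore run on gene ends: the mean of tiles that overlap 1000 bp on either side of the lower- or higher-coordinate end of a gene, 1 of which is its transcription start. Tiles were classed as gene end, gene interior or intergenic in this order. This gave 28537 ends of 20013 genes. A tile can serve 2 genes. Gene bodies (23982 genes) were set for the gene lists before the data were examined; calls of single gene bodies and a window of 2000 bp on either side were added after the data were seen.

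Percent values were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust) with group and title set as terms. A tile was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 10 percentage points, and a gene end at 5 percentage points. Because of the set term, a difference is the lupus mean less the mean of the prediseased samples of Set2, and the other prediseased samples add to the estimate of the spread. Their residual SD over tiles averaged 4.85 percentage points, against 6.82 in prediseased and 7.09 in lupus samples of Set2, so errors of a difference may be understated. Mean methylation was compared with exact two-sided permutation tests over 35 assignments in Set2, 210 over all samples and 20 between sets of prediseased samples. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, and adjusted over 13 lists. The lists were stem cell regulators and markers, myeloid, lymphoid, and erythroid and megakaryocyte differentiation, interferon-stimulated genes, innate sensing and cytokine signalling, glycolysis and mTOR-HIF, cholesterol synthesis, DNA methylation and histone modifying enzymes, cell cycle, imprinted genes, mature lymphocyte markers, and mature granulocyte and macrophage markers. Since the adjusted threshold called no tile, the shares of genomic features were tested with Fisher's exact test on tiles at an unadjusted p under 0.01 and 10 percentage points. Tables were read with data.table (version 1.17.8), pandas 2.3.3 and Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

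The tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule takes the 8 tiles and 6 gene ends with the largest differences in each direction among those called in which all 4 lupus samples lie on one side of the 3 prediseased samples of Set2. Places left open are filled by the smallest unadjusted p among those of the same minimum difference. It also takes the 2 ends with the smallest p in each list, and passes over gene models and predicted genes among the ends. As nothing was called, all named tiles and ends are such fillings. Other tiles named in the text were chosen after their values were seen.

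The fits were tested on simulated data with the spread of these samples, in which 50 tiles each were lowered by 15, 30, 45 or 60 percentage points. Only tiles of higher mean, without those of the largest spread, were lowered, and noise was independent between tiles. Of the lowered tiles, 12%, 62%, 72% and 96% were called, with 19 false calls among the unchanged tiles. For gene ends, also lowered only where the mean was higher, the shares were 28%, 70%, 92% and 100%, with 12 false calls. In both simulations the false calls were a larger share of all calls than the adjusted threshold aims at. Unchanged tiles had an unadjusted p under 0.05 in 6.66% of cases and unchanged gene ends in 6.49%. Alternatives were a logit scale, centring, quantile normalization, other eBayes options, no set term, Set2 alone, a replicate block, no invariant tiles, no sex chromosomes, other minimum differences, other gene regions and leaving out each sample. Sample weights and leaving out the 2 samples with the largest residual spread were added after the data were seen.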

Results

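DNA methylation was measured by reduced representation bisulfite sequencing, which enriches CpG-rich fragments of the genome, in hematopoietic stem and progenitor cells of lupus-prone mice. The cells were bone marrow LSK cells, which lack lineage markers and carry Sca-1 and Kit. The mice were NZB/W hybrids, which develop a lupus-like disease with age. 4 samples came from mice with lupus and 6 from mice before disease, called prediseased. Since the disease comes with age, the lupus mice may have been older. A difference of disease could then not be told apart from one of age. The titles place all 4 lupus samples (S1 to S4) and 3 prediseased samples (S1 to S3) in a set named Set2, while the other 3 prediseased samples (DA1, DA2 and DC) carry no set. The protocol text describes injections of β-glucan or saline, and the labels do not say which of these, if either, the 10 samples received. The deposited values are the percent methylation of 197568 tiles of 1000 bp in every sample. The read depth behind each value is unknown, so no interval for counting error is given.

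Tiles at the ends of genes were less methylated than the rest of the genome covered. Over the 10 samples, mean methylation was 58.6% in the 34683 tiles within 1000 bp of a gene end, 81.2% in the 103880 tiles inside genes and 80.01% in the 59005 intergenic tiles. Most tiles were highly methylated: 133359 had a mean over 80%, 49220 had a mean of 20 to 80% and 14989 had a mean under 20%. Pearson's r between pairs of samples, computed across tiles, ranged from 0.833 to 0.957. Tiles are not independent replicates. Nothing in the labels says that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

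The first question was whether the overall methylation of progenitors differs between lupus and prediseased mice. Mean methylation over all tiles was 76.0% ± 1.58 (SD, n = 4) in lupus and 75.5% ± 0.919 (SD, n = 3) in the prediseased samples of Set2. The difference of 0.486 percentage points was smaller than the spread between samples (exact two-sided permutation test, p = 0.743, where the smallest possible p is 0.0286). Gene ends had 58.1% ± 1.30 (n = 4) in lupus and 57.4% ± 0.521 (n = 3) in prediseased samples of Set2 (exact permutation p = 0.486). X-chromosomal tiles had 75.9% ± 1.81 (n = 4) and 75.5% ± 1.05 (n = 3; exact permutation p = 0.771). The direction of the overall difference depended on which samples entered. It was -1.44 percentage points against all 6 prediseased samples (77.4% ± 2.21, exact permutation p = 0.271), -0.197 without lupus S4 and -0.0145 without prediseased S3.

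**Figure D1:**
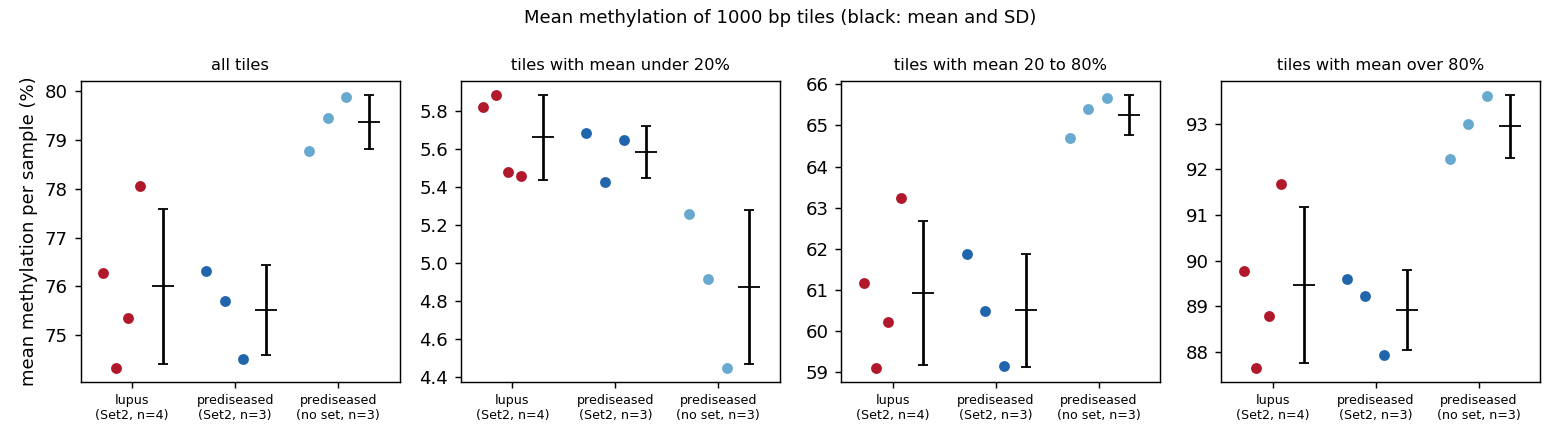
Mean methylation per sample in percent, over all tiles and in tiles with a low, intermediate or high mean over the 10 samples; points are samples, black marks are the mean and SD, and the vertical axes do not start at 0. The 4 lupus samples overlap the 3 prediseased samples of Set2 in each panel, and the 3 prediseased samples without a set lie at 78.8% to 79.9% over all tiles, above the other 7.

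The next comparison asked which regions differ between lupus and prediseased progenitors, with the title set as a term. The widest gap among the named tiles lay at Ccl7, which encodes a chemokine that attracts monocytes. The tile at its lower-coordinate end (mm10 chromosome 11, 82045001 to 82046000) had 12.4% ± 12.04 methylation in lupus (SD, n = 4), 66.9% ± 7.58 in prediseased Set2 samples (n = 3) and 88.1% ± 7.28 in prediseased samples without a set (n = 3). Every lupus sample was at or below 28.9% and every prediseased sample was at or above 60%. A tile inside Lrfn1, which encodes a synaptic adhesion protein (chromosome 7, 28464001 to 28465000), had 12.5% ± 12.3, 55.7% ± 6.58 and 80.5% ± 2.95 in the same order of groups. Neither difference passed the adjusted threshold of limma (differences -54.5 ± 7.21 and -43.2 ± 6.71 percentage points, estimate ± SE, adjusted p = 0.592 and 0.613).

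Across the genome, limma called 0 tiles higher and 0 lower in lupus at an adjusted p under 0.05 and a difference of at least 10 percentage points. The smallest adjusted p was 0.233, and 12688 tiles (6.42%) had an unadjusted p under 0.05. With limma on Set2 alone the smallest adjusted p was 0.960, and 4.365% of tiles had an unadjusted p under 0.05. Other limma fits came closer to the threshold without a call. The smallest adjusted p was 0.0516 without the 2 samples of largest residual spread and 0.0554 without prediseased S1. At an unadjusted p under 0.01 and the same minimum difference, 1105 tiles were higher and 836 lower. The median SE of a tile difference was 4.19 percentage points. In simulated data with this spread, 62% of tiles lowered by 30 percentage points and 96% of tiles lowered by 60 were called, against 12% of tiles lowered by 15. Tiles of lower mean or of the largest spread were not lowered in the simulation, so these shares do not cover them. The 200 lowered tiles also entered 1 fit together, and many changed tiles ease the Benjamini-Hochberg threshold for each. The shares therefore do not hold for data in which few tiles differ, where fewer would be called. Differences of about 15 percentage points in single tiles would mostly not have been detected. Leaving out lupus S2, prediseased S2 or prediseased S3 gave 1 tile lower in lupus each, and these were 3 different tiles. In each the sample left out went against the call (22.2% in lupus S2, and 0% in prediseased S2 and S3), and the prediseased samples without a set were at the lupus level (0%, 0.641% and 0.595%).

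**Figure D2:**
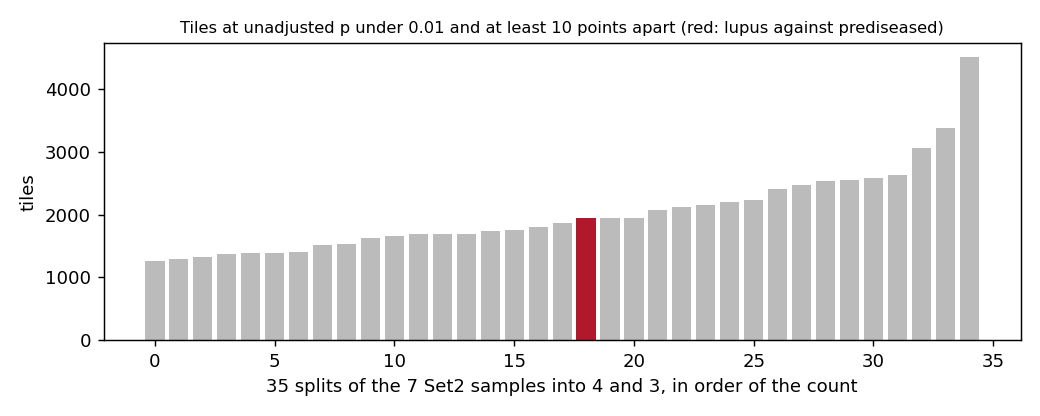
Number of tiles at an unadjusted p under 0.01 and a difference of at least 10 percentage points (vertical axis) for each of the 35 splits of the 7 Set2 samples into 4 and 3 (horizontal axis, in order of the count). The split of lupus against prediseased, in red, has 1941 tiles, and the highest bar has 4502.

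The 8 named tiles higher in lupus had small SDs in lupus and lay mostly near full methylation. A tile inside Mllt1, which encodes a transcription elongation factor subunit (chromosome 17, 56930001 to 56931000), had 96.9% ± 2.28 in lupus and 68.3% ± 8.01 in prediseased Set2 samples, and the prediseased samples without a set were at 94.9% ± 3.81. A tile shared by Pi4ka and Serpind1, genes of a lipid kinase and of a thrombin inhibitor (chromosome 16, 17341001 to 17342000), had 80.2% ± 2.99 in lupus, 50.8% ± 5.01 in prediseased Set2 samples and 80.2% ± 1.94 in those without a set. The intergenic tile at chromosome 7, 29535001 to 29536000, was at 100% in all 4 lupus samples, at 79.4% ± 4.16 in prediseased Set2 samples and at 88.3% ± 4.54 in those without a set. The other 5 lay at chromosome 3, 40454001 (within 1000 bp of an end of Gm30184), chromosome 10, 14218001, chromosome 13, 42346001, chromosome 14, 61596001, and chromosome 17, 6517001 (inside Gm2808), with differences of 19.5, 12.4, 14.1, 13.98 and 19.4 percentage points. In the same order, lupus means were 99.29%, 99.18%, 99%, 99% and 93.52%, and prediseased samples without a set had 96.25%, 93.49%, 97.43%, 98.06% and 98.1%. The tiles on chromosomes 3 and 17 of these 5 were also called between the title sets. Adjusted p of the 8 tiles was 0.362 for the tile on chromosome 3 and 0.592 for the others.

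Among the named tiles lower in lupus, the one with the smallest p lay at an end of Lamb1, a laminin chain gene (chromosome 12, 31266001 to 31267000). It had 0.582% ± 0.426 in lupus and 13.9% ± 2.35 in prediseased Set2 samples, while those without a set were at 1.41% ± 1.47 (adjusted p = 0.233). This tile was also called between the title sets (Set2 higher by 12.4 percentage points, limma adjusted p = 0.0136). A tile inside Agap1, a gene of vesicle trafficking (chromosome 1, 89734001 to 89735000), had 37.4% ± 3.75 in lupus, 70.1% ± 7.69 in prediseased Set2 samples and 44.4% ± 3.83 in those without a set. The intergenic tile at chromosome 15, 93973001 to 93974000, had 35.7% ± 9.60, 72.0% ± 3.203 and 68.4% ± 3.54. The remaining 3, starting at chromosome 5, 59852001, chromosome 2, 167588001 (at an end of Gm31619) and chromosome 2, 37053001, differed by -21.5, -24.3 and -20.4 percentage points. The adjusted p of the named lower tiles ranged from 0.233 to 0.635. In 8 of the 16 named tiles the lupus samples lay apart from all 6 prediseased samples, and in the other 8 at least 1 prediseased sample without a set reached the lupus range or passed it.

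At gene ends, limma called 0 of 28537 ends higher and 0 lower in lupus, with 1757 ends (6.16%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.603. The end with that value was the Ccl7 tile described above. In other limma fits the smallest adjusted p over all ends was 0.0896 without the set term, 0.0955 on the logit scale and 0.925 on Set2 alone. Of the named ends higher in lupus, the end of the zinc-finger gene Zbtb45 had 41.7% ± 4.60 in lupus, 20.3% ± 4.53 in prediseased Set2 samples and 28.8% ± 6.24 in those without a set. Tmem176a, a membrane protein gene, had 20.2% ± 4.63, 8.23% ± 0.784 and 10.02% ± 2.74. The homeobox gene Nkx3-2 had 18.4% ± 1.18, 10.4% ± 2.56 and 10.5% ± 2.30, and the centriole gene Deup1 had 11.9% ± 1.75, 4.86% ± 1.88 and 5.11% ± 0.736. Clcn3, a chloride transporter gene, and Zmym6 differed by 9.01 and 13.8 percentage points, and both were near the lupus level in the prediseased samples without a set (96.2% and 98.7%).

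Of the named ends lower in lupus, Il34, which encodes a ligand of the Csf1 receptor, had 40.9% ± 7.92 in lupus, 61.8% ± 5.07 in prediseased Set2 samples and 53.4% ± 0.813 in those without a set. The homeobox gene Six3 had 47.5% ± 3.53, 64.0% ± 3.30 and 60.3% ± 4.61. Gbe1, the glycogen branching enzyme gene, had 80.5% ± 2.90, 94.1% ± 2.93 and 94.4% ± 3.33. Uba7, which encodes the enzyme that activates the ubiquitin-like protein Isg15, had 2.53% ± 2.95, 13.3% ± 2.19 and 5.38% ± 1.36, and Ttc32 differed by -8.72 percentage points. None passed the threshold (limma adjusted p from 0.603 to 0.797 over the 12 named ends), and in 9 of the 12 the lupus samples lay apart from all 6 prediseased samples. When all tiles in a gene body were averaged, a choice made after the data were seen, limma called 1 of 23982 genes: Serpind1, higher in lupus (difference 29.5 ± 2.54 percentage points, adjusted p = 0.0264). Its body held 1 measured tile, the tile it shares with Pi4ka, in which lupus and the prediseased samples without a set had the same mean of 80.2%. No averaging took place for this gene. Fitted among the tiles, the same values did not pass (SE 4.14 percentage points, limma adjusted p = 0.592), so the call depends on the features fitted together.

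Genes that maintain or mark hematopoietic stem cells were examined first among 13 gene lists. Of 30 measured ends of 19 such genes, 0 passed when adjusted over all ends and 2 passed when adjusted over the list alone. Gata2, a transcription factor gene needed by stem cells (end at chromosome 6, 88193891), had 31.8% ± 2.80 in lupus, 41.2% ± 2.21 in prediseased Set2 samples and 44.6% ± 0.764 in those without a set. Procr, which encodes a stem cell surface receptor (end at chromosome 2, 155751125), had 58.4% ± 3.61, 74.0% ± 4.41 and 86.1% ± 6.25. All 4 lupus samples were below all 6 prediseased samples at both ends. The limma differences were -9.45 ± 2.30 and -15.7 ± 3.84 percentage points (adjusted p = 0.0407 over the list alone and 0.797 over all ends). Both ends stayed past the threshold over the list alone in 1 of the 10 fits that left out a sample, the fit without prediseased DC (adjusted p = 0.0451 and 0.0404), and missed it in the other 9. Without the set term both passed, and on the logit scale, in Set2 alone, under the replicate block and after centring they did not. Over these 15 alternatives the adjusted p over the list alone ranged from 0.00838 to 0.211 for both. Of the 35 splits of the Set2 samples into 4 and 3, 11 gave as many ends past the threshold over a list alone. As a group, the list had a mean of 40.2% ± 0.307 in lupus and 40.9% ± 0.605 in prediseased Set2 samples (camera adjusted p = 0.428, and 0.620 with an estimated correlation). Relative to other ends, its mean difference was -1.30 percentage points, and -0.811 without lupus S4.

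**Figure D3:**
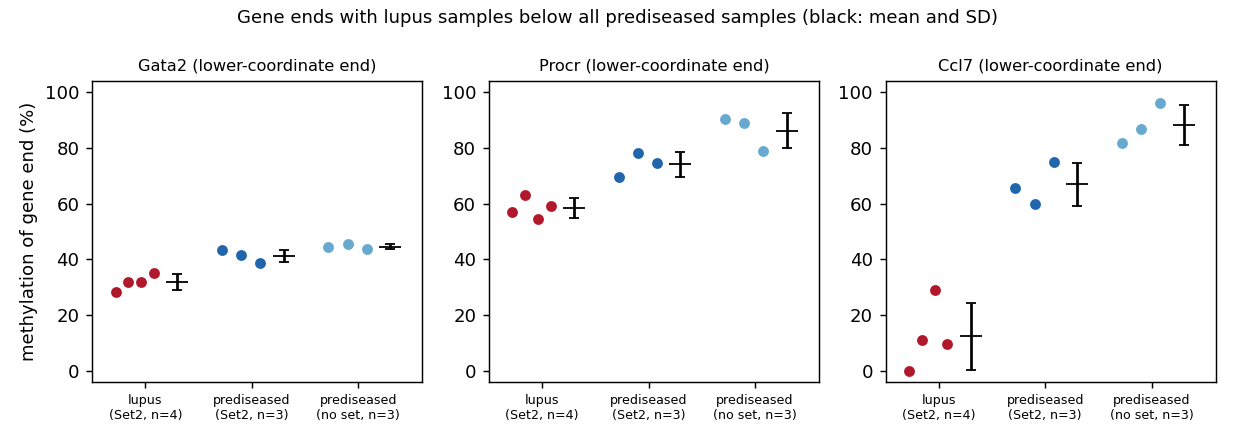
Methylation in percent at the lower-coordinate ends of Gata2, Procr and Ccl7, chosen for display after their values were seen; points are samples, and black marks are the mean and SD of each group. In each panel the 4 lupus samples lie below the 6 prediseased samples, for example at 28.1% to 34.9% against 38.8% to 45.3% at Gata2.

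Interferon-stimulated genes, which are often highly expressed in lupus, had the smallest camera p at gene ends among the 13 lists and did not pass. With fry the stem cell list had the smallest unadjusted p (0.0536, against 0.1235 for interferon-stimulated genes). The 33 measured ends of 23 of these genes averaged 53.1% ± 2.17 in lupus, 55.3% ± 1.88 in prediseased Set2 samples and 58.1% ± 1.72 in those without a set (camera adjusted p = 0.390, and 0.620 with an estimated correlation). Relative to other ends, the mean difference of -2.77 percentage points became -1.60 without lupus S1. At an unadjusted p under 0.05, 3 ends were lower and 0 higher. Isg15, which encodes a ubiquitin-like protein, had 76.6% ± 2.51 at its higher-coordinate end in lupus, 87.5% ± 3.67 in prediseased Set2 samples and 81.9% ± 4.54 in those without a set, and Parp14 had 12.8% ± 5.26, 32.0% ± 1.16 and 30.3% ± 14.1. Innate sensing and inflammatory cytokine genes averaged 55.6% ± 1.65 and 54.5% ± 0.164 (camera adjusted p = 0.984). For this list the mean difference of 1.05 and the median of 0.611 percentage points were positive, while camera gave a downward direction. Its named ends were Syk, a kinase gene (93.9% ± 5.63 in lupus, 81.2% ± 4.56 in prediseased Set2 samples and 96.8% ± 2.86 in those without a set), and Tnfaip3, a gene that restrains NF-kB (90.7% ± 3.67, 99.5% ± 0.902 and 86.1% ± 4.62). At both, the lupus mean lay on the other side of the samples without a set.

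Lineage genes gave no call. Values of single ends are given for lupus, prediseased Set2 samples and prediseased samples without a set, in this order. Myeloid differentiation genes averaged 49.99% ± 1.65 in lupus and 48.9% ± 2.11 in prediseased Set2 samples (camera adjusted p = 0.527), with Zeb2 at 64.1% ± 6.42, 52.5% ± 3.30 and 71.4% ± 6.70 and Cebpe, a granulocyte transcription factor gene, at 90.8% ± 2.88, 84.6% ± 3.66 and 93.5% ± 1.52. Lymphoid genes averaged 53.0% ± 2.16 and 51.1% ± 2.06 (adjusted p = 0.724), with 5 of 34 ends higher and 1 lower at an unadjusted p under 0.05. Among them were Cd79a, part of the B cell receptor (68.0% ± 12.1, 50.3% ± 0.461 and 65.2% ± 3.96), and Bcl11b, a T cell factor gene (2.58% ± 0.808, 0.918% ± 0.568 and 1.11% ± 0.378). Erythroid and megakaryocyte genes averaged 48.6% ± 3.51 and 49.3% ± 3.69 (adjusted p = 0.428), with Gfi1b at 76.9% ± 2.30, 82.9% ± 2.02 and 93.8% ± 1.55 and Epor, the erythropoietin receptor gene, at 34.2% ± 6.54, 51.5% ± 13.9 and 43.2% ± 9.07. Markers of cells outside the LSK gate did not pass either. Mature lymphocyte markers averaged 76.5% ± 2.42 and 73.6% ± 0.692 (adjusted p = 0.428), with Cd8a at 73.6% ± 5.77, 62.9% ± 2.46 and 69.4% ± 1.90 and Cd5 at 27.1% ± 11.02, 12.1% ± 2.40 and 22.7% ± 7.38. Mature granulocyte and macrophage markers averaged 69.8% ± 0.214 and 70.1% ± 3.00 (adjusted p = 0.428), with Csf1 at 86.2% ± 2.6, 92.5% ± 5.09 and 91.1% ± 5.85 and C1qb at 61.3% ± 6.72, 68.3% ± 4.61 and 70.9% ± 1.92.

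The remaining lists covered metabolism, chromatin, growth and imprinting, with single ends given in the same order of groups. Glycolysis and mTOR-HIF genes averaged 52.0% ± 2.11 in lupus and 52.8% ± 1.62 in prediseased Set2 samples (camera adjusted p = 0.428), with the glycolytic enzyme genes Tpi1 at 15.3% ± 2.41, 20.6% ± 0.670 and 23.0% ± 1.76 and Eno1 at 67.3% ± 6.20, 76.0% ± 5.39 and 85.6% ± 3.00. Cholesterol synthesis genes averaged 52.2% ± 2.49 and 50.4% ± 0.868 (adjusted p = 0.724), with Fdft1 at 93.0% ± 5.92, 69.4% ± 18.3 and 93.7% ± 3.87 and Cyp51 at 0.210% ± 0.420, 1.51% ± 1.34 and 0.728% ± 0.311. DNA methylation and histone modifying enzyme genes averaged 36.5% ± 0.665 and 36.0% ± 1.13 (adjusted p = 0.981), with the DNA demethylase gene Tet2 at 0.539% ± 0.210, 1.45% ± 0.515 and 0.374% ± 0.0907 and Setd2 at 83.1% ± 9.81, 95.9% ± 4.09 and 95.3% ± 4.26. The mean and median differences of that list were positive and camera gave a downward direction. Cell cycle genes averaged 41.2% ± 1.32 and 40.4% ± 2.47 (adjusted p = 0.696). Their named ends were Cdkn2a, a gene of cell cycle inhibitors, at 13.9% ± 1.13, 9.19% ± 0.336 and 8.77% ± 3.11, and Mycn at 91.4% ± 7.27, 99.4% ± 1.05 and 98.7% ± 2.31. Imprinted genes averaged 70.9% ± 0.945 and 70.6% ± 1.09 (adjusted p = 0.724), with Dlk1 at 93.2% ± 1.17, 88.3% ± 0.968 and 93.4% ± 3.27 and Peg13 at 53.2% ± 10.6, 68.0% ± 0.996 and 68.6% ± 5.06. Of the 26 ends named from the 13 lists, 7 differed in the opposite direction against the samples without a set (Zeb2, Cebpe, Syk, Tnfaip3, Fdft1, Tet2 and Dlk1). None of the 13 lists passed with an estimated correlation or with fry. Adjusted over each list alone, the 12 lists other than the stem cell list had 0 ends past the threshold in the main fit. This changed with the samples used. In Set2 alone and without prediseased S2, 3 ends of other lists passed in each while the stem cell list had 0, and under the replicate block no list had any. Adjusted over the 406 ends of all lists together, the smallest limma adjusted p in the main fit was 0.44. In simulated data, a lowering of all ends of the imprinted genes by the same 4 percentage points was called (camera adjusted p = 7.38e-06). That simulation had no variation between samples shared by the genes of a list. It therefore does not show that such a change would have been called in these samples.

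Tiles at the nominal threshold lay less often at gene ends than the other tiles tested. Of the 1105 higher tiles, 13.4% were at gene ends (odds ratio 0.725, Fisher's exact test, adjusted p = 0.000285), and of the 836 lower tiles 11.6% were (odds ratio 0.615, adjusted p = 1.50e-05), against 17.6% of the other tiles. Intergenic tiles made up 36.0% and 36.6% (odds ratios 1.32 and 1.36, adjusted p = 3.40e-05 and 6.01e-05). Tiles inside genes made up 50.6% and 51.8% (odds ratios 0.923 and 0.969, adjusted p = 0.221 and 0.652). Odds ratios at gene ends as far from 1 arose in 23 of the 35 splits of the Set2 samples for higher tiles and in 8 for lower tiles, and those of intergenic tiles in 26 and 22. For higher tiles the odds ratio lay below 1 at gene ends and above 1 in intergenic sequence in every split. The p-values of Fisher's test therefore do not tie these shares to lupus. Neighbouring tiles are not independent, and without the set term the odds ratio of higher tiles at gene ends was 1.81. The call of higher tiles at gene ends was lost without lupus S1, S3 or S4 (odds ratios 0.827, 0.865 and 0.858, adjusted p = 0.0736, 0.0832 and 0.135), and that of lower intergenic tiles without lupus S2 (1.11, adjusted p = 0.170). Higher tiles inside genes became a call without the set term (0.690, adjusted p = 0.000178) and without lupus S1, S2, S3 or S4, prediseased DA2 or prediseased S3 (odds ratios 0.759, 0.874, 0.800, 0.818, 0.850 and 0.859). Lower tiles inside genes became a call without lupus S4 or prediseased S1 (0.878 and 0.862).

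The last comparison measured how far the title sets differ among prediseased mice. Mean methylation of the 3 prediseased samples was 75.5% ± 0.919 in Set2 and 79.4% ± 0.556 without a set, a difference of -3.85 percentage points (exact permutation p = 0.100, the smallest that 3 samples against 3 allow). Tiles with a mean over 80% had 88.9% ± 0.873 and 93.0% ± 0.688, while tiles with a mean under 20% had 5.59% ± 0.139 and 4.87% ± 0.408. With the group as a term, limma called 71 tiles higher and 99 lower in Set2, and 13.2% of tiles had an unadjusted p under 0.05. Which direction held more calls depended on the scaling, with 199 higher and 58 lower after centring, and 106 and 243 on the logit scale. The tiles lower in Set2 lay more often at gene ends, with 28 of 99 (28.3%, odds ratio 1.85, Fisher's exact test, adjusted p = 0.0234), and less often inside genes (37.4%, odds ratio 0.538, adjusted p = 0.0198). The 71 tiles higher in Set2 gave no such call (23.9% at gene ends, odds ratio 1.48, adjusted p = 0.321, and 49.3% inside genes, odds ratio 0.877, adjusted p = 0.635). In the 10 fits that left out a sample, the tiles lower in Set2 kept odds ratios of 1.31 to 2.43 at gene ends, with a call in 2 fits, and of 0.263 to 0.658 inside genes, with a call in 6. Both calls held after centring (2.47 and 0.439, adjusted p = 0.00996 and 0.0103). The gene end call was absent on the logit scale (1.097, adjusted p = 0.666) and without trend and robust options (0.953, adjusted p = 0.923), and the odds ratio inside genes was 0.733 in both (adjusted p = 0.0346 and 0.0518). On the logit scale tiles higher in Set2 were the ones called at gene ends (2.32, adjusted p = 0.000623) and were also called inside genes (0.592, adjusted p = 0.0253), and without trend and robust options intergenic tiles lower in Set2 became a call (1.46, adjusted p = 0.0298). Without lupus S4, tiles higher in Set2 were called at gene ends as well (1.90, adjusted p = 0.0451). These fits were added after the data were seen.

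Some tiles were near 0% in one set and near full methylation in the other. The intergenic tile at chromosome 16, 67701001 to 67702000, had 0% in all 7 samples of Set2 and 95.8% ± 3.75 (n = 3) in the samples without a set. Of the 170 tiles, 14 had a prediseased mean of at most 10% in one set and at least 80% in the other, and 37 differed by at least 60 percentage points. A tile inside Cntn4, a neuronal adhesion gene (chromosome 6, 106252001 to 106253000), had 4.25% ± 8.49 in lupus, 10.3% ± 17.9 in prediseased Set2 samples and 89.0% ± 2.47 in those without a set. A tile at an end of Zbtb41 (chromosome 1, 139421001 to 139422000) had 8.53% ± 6.34, 9.81% ± 4.38 and 84.4% ± 12.8. The 88 measured tiles next to these 170 differed between the sets in the same direction by a median of 0.149 percentage points. In 165 of the 170 tiles the lupus mean was closer to the prediseased mean of Set2 than to that without a set. The number of tiles called between the sets fell to 58 without prediseased DA1, of which 44 were among the 170, and ranged up to 211 when other samples were left out. Of the 170, 39 were called in all 10 of these fits, among them the 3 described here, and 14 in none. These tiles were singled out after their values were seen.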

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

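The counts of splits for intergenic odds ratios, for tiles, gene ends and lists past the adjusted threshold, for ends adjusted over a list alone and for tiles apart from all 6 prediseased samples, and the test of a shift common to all tiles, were chosen after the results were seen; the other tests were set before.

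Of 158 groups of samples examined, 8 had 1 sample flagged as far from the others. Chance gives about 1 in 20 where values are not tied. Where the other samples are tied at 0% or 100%, any departure is flagged however small, so that rate does not apply. In 5 of them the other samples of the same group were all at 100%: lupus S4 at 97.1% in the tile at chromosome 3, 40454001, lupus S3 at 96.0% in the tiles at chromosome 13, 42346001, and chromosome 14, 61596001, prediseased DA2 at 87.5% in the tile at chromosome 2, 37053001 and lupus S3 at 90.0% at the end of Zmym6. Lupus S2 had 0.840% at the end of Cyp51, where the other lupus samples had 0%. Lupus S2 had 64.9% at the lower-coordinate end of Cd8a, where the others had 76.2% to 76.9%. Lupus S4 had a mean of 53.8% over the erythroid and megakaryocyte genes, where the others had 46.2% to 47.3%.

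The first pattern is the small number of differences between lupus and prediseased samples, and chance could not be excluded for the 1941 nominal tiles, a number reached by 17 of the 35 splits of the Set2 samples into 4 and 3 (highest other 4502). For the 0 tiles, 0 gene ends and 0 lists past the adjusted threshold the splits decide nothing, since each of the 35 must reach 0 (highest others 34 tiles, 41 ends and 1 list). The split with 4502 set lupus S1, lupus S4 and prediseased S3 against the other 4, and these 3 have the highest shares of tiles at exactly 100% in Set2 (12.3%, 8.87% and 7.83%). This match was seen after the split was picked as the highest, and whether it exceeds chance was not tested. The 59 tiles with a gap of at least 10 percentage points between lupus and all 6 prediseased samples were reached by 4 of the 35 splits (highest other 103), and the 2 ends past the threshold over a list alone, Gata2 and Procr, by 11 (highest other 3). All counts of splits include the split of lupus against prediseased itself. A lupus difference shared by both prediseased sets stays open: 90.9% of the nominal tiles from Set2 had the same direction against the samples without a set, a share reached by 14 splits (highest other 94.3%), and since each split sets the same 4 samples against both sets, the share is high in every other split too (at least 72.1%). A value inside that range, set before the test as speaking against such a difference, therefore does not exclude it.

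The shares of genomic features belong to the same pattern. An odds ratio at gene ends as far from 1 was found in 8 splits for lower tiles (real 0.615, farthest other 0.434) and in 23 for higher tiles (real 0.725, farthest other 0.467). In intergenic sequence it was found in 22 splits for lower tiles (real 1.36, farthest other 1.71) and in 26 for higher tiles (real 1.32, farthest other 1.69). For higher tiles, every split gave odds ratios below 1 at gene ends (0.467 to 0.857) and above 1 in intergenic sequence (1.01 to 1.69). For lower tiles most splits did so, with exceptions up to 1.13 at gene ends and down to 0.968 in intergenic sequence. These directions are therefore not particular to lupus, and chance could not be excluded.

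The second pattern is the lower methylation of prediseased samples in Set2. A shift common to all tiles is argued against as the whole cause, because tiles with a mean under 20% went the other way: they were 0.714 percentage points higher in Set2, while tiles with a mean over 80% were lower (difference -4.03), and in both classes all 3 samples of one set lay apart from all 3 of the other. Less complete bisulfite conversion in the samples without a set would raise the tiles with a mean under 20% in those samples, where they were lower (difference -0.714 percentage points). Library preparation, the CpGs covered, and differences between the mice that the labels do not give stay open and were not tested, and the title set cannot be separated from any of them.

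The third pattern is that the tiles that differ between sets stand alone. Of the 170 tiles, 30 had another within 1000000 bp, fewer than the median of 38 in 1000 random draws of as many tiles, which argues against inherited segments that differ between the mice. In the 88 adjacent measured tiles the difference in the same direction had a median of 0.149 percentage points (quartiles -3.04 and 3.75), against a median size of 45.4 in the tiles themselves, which argues against a regional change wider than 1 tile. Single sequence variants at a CpG, or different CpGs read in the 2 sets, may remain as explanations and need values per CpG, which were not analysed here. As NZB/W hybrids, the mice of both sets would share inherited variants unless their parents differed, which limits the first of these. Beyond inherited segments and regional change, no biological explanation was tested, as the labels name no difference between the mice of the sets.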

How the results depend on the processing

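Sample weights, calls of single gene bodies, the 2000 bp window, the fits without the 2 samples of largest spread, the block for mean methylation and for gene lists, centring for the stem cell list, and all alternatives for the features of tiles that differ between sets were added after the data were seen. Counts of tiles and gene ends called in lupus stayed at 0 except as given here, and the 54 named tiles and ends kept their direction and stayed short of the adjusted threshold under all 15 settings applied to them. The 16 tiles and 12 ends chosen with lupus on one side of Set2 prediseased samples could not reverse when a sample was left out or under the block. Set2 alone, or leaving out a sample without a set, leaves the difference unchanged. The kept directions are therefore no evidence of stability. Tiles lower in lupus ranged from 0 to 1 when a sample was left out. The tile was at chromosome 1, 189066001 (intergenic) without lupus S2, at chromosome 11, 117870001 (an end of Tha1) without prediseased S2 and at chromosome 7, 30092001 (intergenic) without prediseased S3. Gene bodies gave 1 gene higher, Serpind1, from 1 tile that was not called among the tiles.

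Tiles that differ between sets numbered 170, and 349 on the logit scale, 257 after centring, 351 without trend and robust options, 1209 with sample weights and 58 to 211 when a sample was left out. Of the 170, 109, 125, 161 and 170 were also called under those 4 settings, 91 without the 2 samples of largest spread and 44 to 125 when a sample was left out. Tiles higher and lower in Set2 numbered 71 and 99 in the main fit, 106 and 243 on the logit scale, and 108 and 243 without trend and robust options. After centring they numbered 199 and 58, so the excess of lower tiles reversed. The difference in mean methylation was 0.486, and -1.44 over all 10 samples, -0.197 under the block, the value without lupus S4, and -0.197 to 1.04 when a sample was left out.

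No list passed under any alternative. Relative to other ends, the mean difference reversed for myeloid genes without the set term (-0.180), for gene bodies of innate sensing genes (-0.558) and of granulocyte and macrophage markers (0.409), and under the block for DNA methylation enzymes (0.0785) and imprinted genes (0.213), which are their values without lupus S4. Leaving out a sample gave -0.399 to 1.14 for myeloid, -3.05 to 0.158 for erythroid and megakaryocyte, -0.547 to 0.396 for DNA methylation enzyme, -1.07 to 1.43 for cell cycle and -1.04 to 0.2303 for imprinted genes, and -2.23 to 0.260 for granulocyte and macrophage markers. The other lists kept their sign, with -3.51 to -1.60 for interferon, -1.65 to -0.811 for stem cell, 0.451 to 2.11 for lymphoid, -1.99 to -0.767 for glycolysis, 0.195 to 0.679 for innate sensing, 0.762 to 1.64 for cholesterol and 1.74 to 2.75 for mature lymphocyte genes. Odds ratios without the set term were 1.81 (higher tiles, gene ends), 0.954 (higher, intergenic) and 1.02 (lower, gene interior). With no minimum difference that of higher tiles in gene interiors was 1.06, and with the 2000 bp window that of lower tiles there was 1.02. Leaving out a sample gave 0.618 to 0.865 for higher and 0.531 to 0.831 for lower tiles at gene ends, 1.25 to 1.54 and 1.11 to 1.61 for intergenic tiles and 0.759 to 1.02 and 0.862 to 1.03 in gene interiors. The higher gene end call was lost in 3 of 10 such fits and the lower intergenic call in 1, while gene interiors became a call in 6 for higher and 2 for lower tiles. Apart from the block, the cause of these changes was not tested.

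The replicate numbers S1 to S3 do not pair lupus and prediseased samples: correlations of the deviations of same-numbered samples were -0.066, -0.019 and -0.039. With the replicate block, 0 tiles, 0 gene ends and 0 lists were called, as without it. Lupus S4 has no partner and carries no weight under the block, so its differences equal those without S4 in all 14 results compared (mean methylation and 13 lists). The missing-value alternative could move nothing, since no value is missing. The promoter window of unequal sides and a coverage minimum were not run, for want of strand and coverage, and the tile nearest a gene end stood in for that nearest the transcription start. Unknown depth limits every single-tile value.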

Other observations

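Over gene bodies in place of gene ends, lymphoid genes had an unadjusted camera p of 0.0415 and stem cell genes of 0.0514, and neither passed when adjusted over the 13 lists (adjusted p = 0.290 for both).

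The table holds 9 tiles of the Y chromosome, between 10708001 and 90808000, although the protocol text speaks of female mice. If the mice are female, the reads in these tiles come from other sequence, and the values are not methylation of the Y chromosome. The origin of the reads could not be tested. Mean methylation of the 9 tiles, examined after the values were seen, was 90.2% ± 1.25 in lupus (n = 4), 92.5% ± 0.616 in prediseased Set2 samples (n = 3) and 93.7% ± 0.316 in those without a set (n = 3). All 4 lupus samples (88.7% to 91.4%) lay below all 6 prediseased samples (91.95% to 94.0%). The exact two-sided permutation p was 0.0571 within Set2 and 0.00476 over all 10 samples, the smallest that 210 assignments allow. Adjusted over 21 chromosomes these were 0.771 and 0.100, and the comparison over all 10 samples leaves the title set out of account. None of the 9 tiles passed limma's adjusted threshold.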
